A study of Homo sapiens with 12 samples.

How the data were processed

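Total RNA from 12 human blood progenitor samples was measured on the Affymetrix Human Exon 1.0 ST array, 1 array per sample. Each transcript is covered on this platform by several probe sets, most of them placed in single exons. Per the labels, CD34+ PBCs were kept in X-VIVO10 medium with human serum albumin, and differentiation along 3 lineages was induced with growth factors. The labels name 3 arrays in each of 4 groups, called CD34, Erythropoietic, Granulopoietic and Megakaryopoietic. RNA was extracted with a column kit, and biotin-labelled targets were made with the WT cDNA protocol for exon arrays, per the labels' protocols.

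The deposited values are RMA values per probe set, per the submitters' processing notes, which name RMA and give no version, probe-set list or settings. RMA subtracts background, normalises arrays by quantiles and summarises probes by a robust fit. The deposited values were read as log2 intensities because they ran from 0.758 to 14.646; the scale is not named in the labels, and every log2 difference and fold below rests on that reading. Array medians over all probe sets ranged from 5.267 to 5.889, so the arrays were not equal in distribution over the deposited probe sets. No genome build or exon position came with the values, and probe sets are named by their identifiers. An array has no count depth, and the number of arrays limits the precision.

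The table held 287329 probe sets, of which 261273 named 1 gene symbol, 9155 named several and 16901 named none. Symbols were brought up to date with a table of current and older names: 14546 were current, 2300 were older and were replaced, and 95 were kept as given. The 406 probe sets of Y-chromosome genes, XIST and TSIX were left out because the samples are human. A further 207 symbols whose probe sets lay in separate runs of the table, more than 100 positions apart, were left out because such a symbol can join more than 1 locus; this step was chosen after the distribution of probe sets had been seen. For each remaining symbol with at least 3 single-gene probe sets, a median polish of at most 20 iterations over its probe sets gave 1 gene value per array. This left 16002 genes with 256352 probe sets, a median of 13 per gene. Genes of families with near-identical members, such as HBB and HBD, the CEACAM genes and the MCM and OAS families, can share signal between probes and are reported with that uncertainty.

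Gene values were compared in limma 3.58.1 under R 4.3.3, with the data.table package (version 1.17.8) for reading files. One linear model held the 4 group means over all 12 arrays, with the spread shared between groups and moderated by an intensity trend. A moderated F test asked which genes differed among the groups, and moderated contrasts compared each lineage with CD34 and each pair of lineages. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called changed, and those with at least a 2-fold difference were counted as well. A lineage-specific gene was called at least 2-fold higher in 1 group than in each of the other 3. Standard errors are those of limma; SDs are over the 3 arrays of a group.

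Unequal change of a gene's probe sets was tested with limma's diffSplice and the Simes method. The test used probe sets brighter than the median probe set (quantile 0.5) and genes with at least 3 of these and a value above the median gene in both groups compared. This test takes 1 variance per gene, so a test with a variance for each probe set was added after the data had been seen, and the genes called by both tests are the ones described. A deviation is the difference of a probe set minus that of the other bright probe sets of its gene. A deviating probe set can reflect exon use, and it can also reflect a probe set that is saturated, cross-hybridising or annotated to the wrong gene.

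The 20 gene lists and a list of 28 genes known to be spliced by cell type were fixed before the data were examined. The 20 lists hold globin chains and globin chaperone, heme synthesis and iron uptake, red cell membrane and skeleton, erythroid and megakaryocytic transcription factors, platelet surface receptors, platelet granule and cytoskeletal proteins, primary granule proteins, secondary granule proteins and neutrophil maturation, myeloid transcription factors, phagocyte NADPH oxidase, eosinophil, basophil and mast cell markers, monocyte, macrophage and dendritic cell markers, stem and progenitor cell genes, T and NK cell markers, B cell markers, cell cycle, cholesterol synthesis, interferon response, immediate early and stress genes, and splicing regulators. They hold 338 genes, of which 5 are in more than 1 list. Members without a tested gene value, among them HBA1, HBA2, HBG1, HBG2, GYPA, MPL, RNASE2, RNASE3, NCF1, NCF2, CDK1 and STAT1, could not be reported. Each list was counted gene by gene, with p-values adjusted over all genes and over the list alone, and set against the other genes with camera at a preset correlation of 0.01 and, as an alternative, at an estimated correlation. Camera p-values were adjusted over the 20 lists of a comparison. A further 5 lists, of HOXA and HOXB cluster genes, serine synthesis, one-carbon and amino acid response, glycolysis, cytosolic aminoacyl-tRNA synthetases, and lysosome and antigen presentation, were chosen after the data had been seen.

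The genes named in the text follow a rule fixed with the lists. It takes the 8 largest increases and the 8 largest decreases of each lineage against CD34 among called genes without overlap of the 3 values against 3, up to 4 members of each list with the largest difference, the 8 strongest genes of each lineage-specific set, the 5 genes with the lowest Simes p per exon comparison, and the receptors EPOR, CSF3R, KIT and FLT3 with CD34 itself. Genes named outside the rule are marked where they appear. Overlap between lineages was set beside 100 simulated data sets of unchanged groups against the shared CD34 arrays and beside the overlap of independent lists.

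Each step was tested on simulated data with independent noise of the observed spread. Every group started from the CD34 mean of a gene, or in the exon test from a probe set's mean over all arrays. For gene values there were 200 changed genes among the 16002. At a log2 difference of 2 the gene test recovered 100% of them in every comparison, and at a log2 difference of 1 it recovered 94.5% for Erythropoietic against CD34, 95.5% for Granulopoietic against CD34 and 91% for Megakaryopoietic against CD34. At a log2 difference of 0.5 these shares were 3.5%, 1% and 4%. In the data 33.3%, 27.6% and 47.8% of genes changed in these comparisons. The adjusted threshold is stricter when few genes change, so these shares do not give the recovery in the data. For Megakaryopoietic against CD34, with 200 genes among 7696 given 1 deviating probe set of log2 2, diffSplice recovered 97% and called 359 unchanged genes, while the test with a variance for each probe set recovered 80.5% and called 5 unchanged genes. At a deviation of log2 1, over 7684 genes, these shares were 40% and 0.5%, so small deviations in single probe sets were mostly missed by the pair of tests together.

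The alternatives tried were gene means in place of median polish, bright probe sets only, at least 6 probe sets per gene, removal of the genes with the lowest mean values, quantile normalisation, centring of each array on its median gene or on genes not used in blood cells, fits without the intensity trend, with robust moderation or on the 6 arrays compared, the replicate number as a block, leaving out each array, other thresholds for the exon test, and the symbols of more than 1 locus kept. Groups were compared with 3 arrays each, and nothing in the labels says whether replicates came from separate donors or separate cultures, so p-values measure only the spread between these arrays.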

Results

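Expression was measured at exon resolution in 12 arrays of human CD34+ blood progenitor cells, 3 in each of 4 groups. The CD34 group was cultured in serum-free medium with albumin, and its labels name no lineage growth factor. All 3 lineage media held stem cell factor (SCF) and Flt3-ligand at 50 ng/ml each. The Erythropoietic medium also held interleukin-3 at 10 ng/ml and erythropoietin at 10 U/ml. The Granulopoietic medium also held interleukin-3, G-CSF and GM-CSF at 10 ng/ml each. The Megakaryopoietic medium held thrombopoietin at 20 ng/ml and no interleukin-3. The series was set up to compare expression and exon use among the starting cells and the 3 lineages derived from them.

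Values are log2 intensities, a scale read from the values themselves, as the labels do not name it. Array medians over all probe sets were 5.691 to 5.732 for CD34 and 5.751 to 5.801 for Erythropoietic. They were 5.889, 5.872 and 5.531 for Granulopoietic replicates 1, 2 and 3, and 5.267, 5.369 and 5.482 for Megakaryopoietic replicates 1, 2 and 3. Correlations between arrays of a group were taken across the probe sets of tested genes. They describe the arrays and do not treat probe sets as independent replicates. They were 0.963 to 0.966 in CD34, 0.97 to 0.971 in Erythropoietic, 0.939 to 0.967 in Granulopoietic and 0.96 to 0.97 in Megakaryopoietic. The median SD of a gene over 3 arrays was 0.112, 0.096, 0.209 and 0.168 in the same order.

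Which genes separated the 4 groups was asked first. On the first principal component, which held 61.8% of the variance, the Megakaryopoietic arrays scored 83.1 to 96.1 and the other 9 arrays -46.3 to -18.5. On the second component, which held 21.5%, the CD34 arrays scored -51.9 to -51.5, the Erythropoietic arrays 31.7 to 32.5, the Granulopoietic arrays 5.7 to 20.3 and the Megakaryopoietic arrays 1.2 to 11.9. In limma's moderated F test 9585 of 16002 genes, or 59.9%, differed among the groups at an adjusted p under 0.05.

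**Figure D1:**
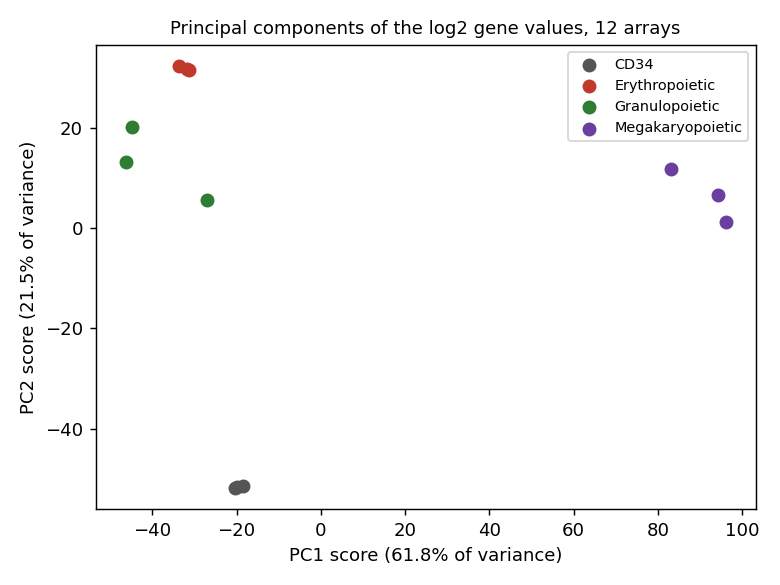
Scores of the 12 arrays on the first (61.8% of variance) and second (21.5%) principal components of 16002 log2 gene values, 1 point per array and 1 colour per group. The 3 Megakaryopoietic arrays lie at 83.1 to 96.1 on the first component, and the CD34 arrays at -51.9 to -51.5 on the second.

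Genes at least 2-fold higher in 1 group than in each of the other 3 numbered 296 for CD34, 71 for Erythropoietic, 120 for Granulopoietic and 659 for Megakaryopoietic. The strongest CD34-specific genes were the calcium-binding proteins S100A12, S100A8 and S100A9, the interferon-induced GTPase gene GBP4, DNTT, which encodes the terminal transferase of lymphoid progenitors, the matrix proteoglycan gene VCAN, the homeobox gene HOXA5 and the adaptor gene SCIMP. DNTT had a log2 value of 6.66 ± 0.18 (SD, n = 3 arrays) in CD34 against 2.85 ± 0.11 in Erythropoietic, 3.01 ± 0.13 in Granulopoietic and 2.81 ± 0.087 in Megakaryopoietic arrays. The monocyte markers VCAN, CD14, FCN1 and CX3CR1 and the B cell markers CD79A and CD22 also fell from CD34 in each of the 3 lineages. The labels give no purity for the CD34 cells, so how far the falls against CD34 reflect other cells in those samples is unknown. The strongest Erythropoietic-specific genes were AHSP, which encodes the chaperone of alpha globin, SLC4A1 (the band 3 anion exchanger), ALAS2 (the erythroid enzyme that starts heme synthesis), the carbonic anhydrase gene CA1, HBB (beta globin), TLCD4, CDH1 (E-cadherin) and GALNT5. AHSP reached 8.56 ± 0.28 in Erythropoietic arrays against 2.95 ± 0.14, 4.07 ± 0.19 and 2.93 ± 0.29 in CD34, Granulopoietic and Megakaryopoietic arrays. The strongest Granulopoietic-specific genes were BPI, ELANE, CTSG and PRTN3, which encode proteins of neutrophil primary granules, with SERPINB10, CEACAM6, CD24 and CSTA. ELANE, the gene of neutrophil elastase, reached 12.25 ± 0.23 against 6.81 ± 0.12 in CD34 and 7.84 ± 0.087 in Erythropoietic arrays. The strongest Megakaryopoietic-specific genes were CD226, VWF (von Willebrand factor), the receptor gene CLEC1B, the phosphodiesterase genes PDE3A and PDE5A, ABCC3, PKHD1L1 and the heparanase gene HPSE. VWF reached 12.02 ± 0.11 against 6.04 ± 0.016 in CD34 arrays. Without Granulopoietic replicate 2 the Erythropoietic-specific set held 114 genes in place of 71, and with bright probe sets only the Granulopoietic-specific set held 74 in place of 120, 68 of them shared.

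**Figure D2:**
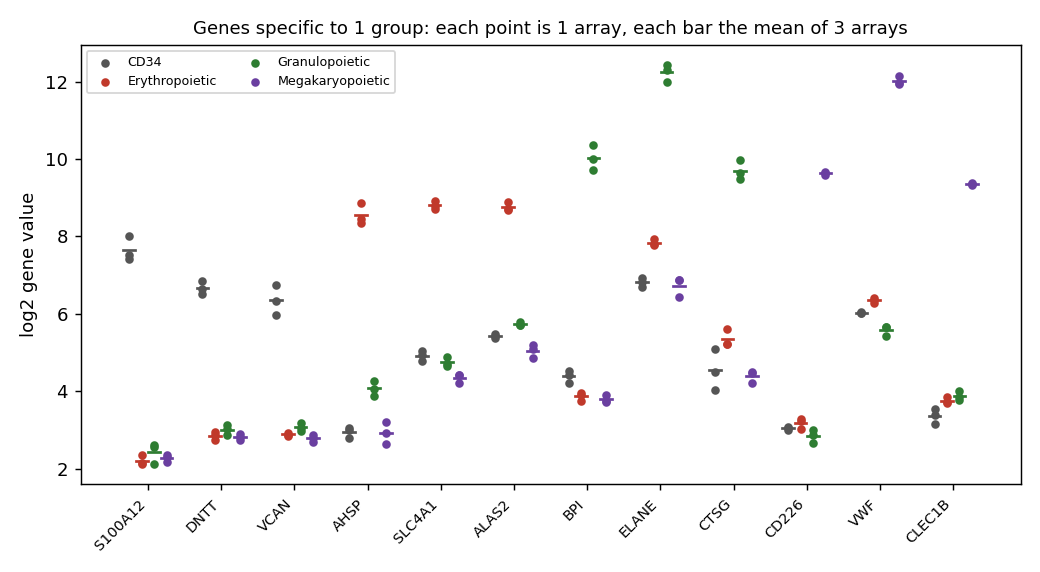
Log2 gene values of 3 genes specific to each group, with 1 point per array, 1 colour per group and a bar at the mean of the 3 arrays. DNTT stands at 6.66 in CD34 arrays and ELANE at 12.25 in Granulopoietic arrays, while VWF stands at 12.02 in Megakaryopoietic arrays.

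The comparison of Erythropoietic with CD34 arrays asked what changed in cells given erythropoietin with SCF, Flt3-ligand and interleukin-3. In each comparison with CD34 the factors of a medium came together, so a change cannot be assigned to a single factor. Genes of the red cell programme rose: AHSP rose by a log2 difference of 5.61 ± 0.18 (SE, n = 3 against 3 arrays), RHAG, which encodes a channel of the Rh complex, by 4.71 ± 0.19, CA1 by 4.2 ± 0.15, SLC4A1 by 3.89 ± 0.12 and HBB by 3.77 ± 0.15. Mitotic genes also rose, with TOP2A (topoisomerase II alpha) at 5.08 ± 0.29, CCNA2 (cyclin A) at 4.9 ± 0.29 and the kinase gene PLK1 at 4.66 ± 0.31. The eosinophil granule genes EPX (eosinophil peroxidase) and CLC (galectin-10) rose by 5.56 ± 0.24 and 4.58 ± 0.29. The largest decreases were in S100A8, which fell by 6.29 ± 0.53, S100A12, which fell by 5.45 ± 0.17, GBP4, which fell by 4.04 ± 0.2, and DNTT, which fell by 3.81 ± 0.12. S100A9, GLIPR1, CXCL16 and HLF, a transcription factor gene of stem cells, fell by 3.76, 3.7, 3.62 and 3.55.

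Of the measured members of each list, 16 of 19 red cell membrane and skeleton genes rose and 0 fell, among them XK at 3.52 ± 0.19 (adjusted p = 0.0218 with an estimated correlation). In heme synthesis and iron uptake 12 of 13 rose, with ALAS2 at 3.35 ± 0.12, CPOX at 2.42 ± 0.29, FECH, which encodes ferrochelatase, at 2.41 ± 0.18 and ABCB6 at 1.95 ± 0.18 (adjusted p = 0.0635 with an estimated correlation). Of 7 globin chains and globin chaperone genes 5 rose, HBD by 3.52 ± 0.13, though HBB and HBD are close in sequence and can share signal (adjusted p = 0.0635 with an estimated correlation). Among 16 erythroid and megakaryocytic transcription factors 7 rose and 5 fell, with GATA1 at 2.55 ± 0.11, KLF1 at 1.45 ± 0.13 and E2F2 at 1.45 ± 0.16 against ETV6 at -1.49 ± 0.11. With arrays centred on the median gene the counts were 6 and 6. All 25 cell cycle genes rose (adjusted p = 0.0639 with an estimated correlation). All 13 cholesterol synthesis genes rose, with HMGCS1 at 3.98 ± 0.26, SQLE at 2.52 ± 0.18 and LSS at 2.44 ± 0.11 (adjusted p = 0.0635 with an estimated correlation).

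Of 24 stem and progenitor cell genes 19 fell and 2 rose, including HOXA5 at -3.44 ± 0.27, PROM1 at -3.22 ± 0.31 and BAALC at -3.13 ± 0.27 (adjusted p = 0.0635 with an estimated correlation). CD34 itself fell by 2.04 ± 0.3 and the receptor gene FLT3 by 3.05 ± 0.21, while KIT, the SCF receptor, rose by 0.95 ± 0.26 and the erythropoietin receptor EPOR by 1.58 ± 0.13. Of 14 monocyte, macrophage and dendritic cell markers 8 fell and 0 rose, led by VCAN at -3.47 ± 0.16, CD14 at -3.08 ± 0.22 and FCN1 at -2.99 ± 0.17 (adjusted p = 0.00686 with an estimated correlation). Of 21 genes of secondary granule proteins and neutrophil maturation 13 fell and 1 rose, and CSF3R, the G-CSF receptor, fell by 3.02 ± 0.15 (adjusted p = 0.0187 with an estimated correlation). Of 11 myeloid transcription factors 6 fell and 1 rose, with IRF8 at -2.1 ± 0.19, KLF4 at -1.7 ± 0.13, CEBPB at -1.27 ± 0.18 and SPI1 (the factor PU.1) at -1.01 ± 0.14 (adjusted p = 0.0511 with an estimated correlation). Of 11 primary granule proteins 8 rose and 2 fell, with MPO at 1.34 ± 0.17, CST7 at 1.23 ± 0.11 and SERPINB10 at 1.22 ± 0.16 against LYZ at -1.88 ± 0.23 (adjusted p = 0.107 with an estimated correlation). Of 9 eosinophil, basophil and mast cell markers 6 rose and 0 fell, HDC by 1.43 ± 0.12 and PRG3 by 1.37 ± 0.18 among them (adjusted p = 0.0635 with an estimated correlation). Of 4 phagocyte NADPH oxidase genes 1 rose and 2 fell, the latter including CYBB by 3.21 ± 0.3.

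B cell markers fell in 6 of 8 cases and rose in 1, with CD79A at -2.67 ± 0.16 and CD22 at -1.85 ± 0.12 (adjusted p = 0.0635 with an estimated correlation). Among 14 T and NK cell markers 1 fell, the granule gene NKG7 at -1.01 ± 0.15, and the list's median (0.03) and mean (-0.05) differed in sign. Of 15 interferon response genes 9 fell and 2 rose, OAS2 at -2.41 ± 0.15, OAS1 at -1.85 ± 0.2 and MX2 at -1.5 ± 0.16 (adjusted p = 0.0775 with an estimated correlation). Of 16 immediate early and stress genes 9 fell and 2 rose, with ZFP36 at -2.29 ± 0.12 and JUNB at -1.48 ± 0.11 (adjusted p = 0.0635 with an estimated correlation). Platelet surface receptors rose in 7 of 17 cases and fell in 1, with ITGB3 at 3.39 ± 0.11, ITGA2B at 2.87 ± 0.1 and P2RX1 at -1.43 ± 0.14. Platelet granule and cytoskeletal proteins rose in 8 of 18 and fell in 4, with LTBP1 at 3.2 ± 0.19 and PPBP at 1.49 ± 0.17. Of 29 splicing regulators 6 rose and 4 fell, SRSF5 by 1.27 ± 0.14, counts that became 7 and 7 with arrays centred on the median gene and 8 and 9 with quantile normalisation. Adjusted over the list alone, 1 more gene fell in each of the lists of erythroid and megakaryocytic transcription factors, myeloid transcription factors, eosinophil markers, monocyte markers, stem and progenitor genes and immediate early genes, and the other 14 lists kept their counts.

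In limma 5327 genes (33.3%) changed, 2991 higher and 2336 lower, of which 938 and 767 differed at least 2-fold, with a median SE of 0.14. With arrays centred on the median gene the split was 2719 higher and 2928 lower, so the larger side depends on the scaling. The values of the 3 arrays did not overlap with the other 3 for 55.9% of genes, where chance gives 10%. Camera called 14 of the 20 lists at the preset correlation and 3 with an estimated one, and other splits of the same 6 arrays gave up to 12 lists at the preset value, so those calls carry little weight beside the counts of members.

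The comparison of Granulopoietic with CD34 arrays asked what changed in cells given G-CSF and GM-CSF with SCF, Flt3-ligand and interleukin-3. Primary granule genes and the eosinophil granule genes EPX and CLC were among those that rose most. EPX rose by 6.8 ± 0.24, BPI, an antibacterial granule protein, by 5.63 ± 0.16, ELANE by 5.44 ± 0.15, SERPINB10 by 5.19 ± 0.16, the cathepsin gene CTSG by 5.17 ± 0.23, CLC by 5.13 ± 0.29 and the proteinase gene PRTN3 by 5.02 ± 0.12. TOP2A rose by 4.4 ± 0.29. The largest decreases were in S100A12, which fell by 5.23 ± 0.17, S100A8, which fell by 4.06 ± 0.53, GBP4, which fell by 3.89 ± 0.2, DNTT, which fell by 3.65 ± 0.12, and the proto-oncogene MYCN, which fell by 3.62 ± 0.24.

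Of 11 primary granule proteins 10 rose and 0 fell (adjusted p = 0.00384 with an estimated correlation). Among 21 genes of secondary granule proteins and neutrophil maturation 4 rose, CEACAM6 by 4 ± 0.15, and 11 fell, among them S100A8, S100A9 and S100A12, which are also high in monocytes (adjusted p = 0.0485 with an estimated correlation). CSF3R differed by -0.21 ± 0.15, which did not pass (adjusted p = 0.324). Myeloid transcription factors rose in 5 of 11 cases and fell in 3. The granulocyte factors CEBPE, GFI1 and CEBPA rose by 2.97 ± 0.14, 2.14 ± 0.12 and 1.47 ± 0.13, and the monocyte factor KLF4 fell by 1.03 ± 0.13. Of 9 eosinophil, basophil and mast cell markers 6 rose, the mast cell gene CPA3 by 1.12 ± 0.23 (adjusted p = 0.074 with an estimated correlation). Of 4 phagocyte NADPH oxidase genes NCF4 rose by 1.01 ± 0.18 and CYBB fell by 2.08 ± 0.3. All 25 cell cycle genes rose (adjusted p = 0.0929 with an estimated correlation). All 13 cholesterol synthesis genes rose, with HMGCS1 at 3.63 ± 0.26 and DHCR7 at 2.93 ± 0.13 (adjusted p = 0.074 with an estimated correlation).

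Of 24 stem and progenitor cell genes 20 fell and 0 rose, including NPR3 at -3.16 ± 0.26, HOXA5 at -3.14 ± 0.27, CD34 at -2.92 ± 0.3 and HLF at -2.84 ± 0.24 (adjusted p = 0.0485 with an estimated correlation). Of 14 monocyte, macrophage and dendritic cell markers 8 fell and 0 rose, VCAN at -3.28 ± 0.16, CX3CR1 at -3.03 ± 0.22 and CD14 at -2.45 ± 0.22 (adjusted p = 0.0068 with an estimated correlation). Of 16 erythroid and megakaryocytic transcription factors 9 fell and 3 rose, MEIS1 at -2.63 ± 0.24 (adjusted p = 0.215 with an estimated correlation). Red cell genes moved up by less than in the Erythropoietic arrays. In red cell membrane and skeleton 11 of 19 rose, RHAG by 1.7 ± 0.19 (adjusted p = 0.215 with an estimated correlation). In globin chains 4 of 7 rose, AHSP by 1.12 ± 0.18 (adjusted p = 0.215 with an estimated correlation), and in heme synthesis and iron uptake 5 of 13, CPOX by 1.26 ± 0.29. FLT3 fell by 1.96 ± 0.21, KIT differed by -0.38 ± 0.26, which did not pass (adjusted p = 0.318), and EPOR rose by 0.51 ± 0.13 (adjusted p = 0.0101), a call lost without CD34 replicate 1 (0.4, adjusted p = 0.0531).

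B cell markers fell in 6 of 8 cases, CD79A by 2.64 ± 0.16, and rose in 1, IGLL1, a surrogate light chain gene, by 2.36 ± 0.15 (adjusted p = 0.0856 with an estimated correlation). Of 14 T and NK cell markers 1 rose, NKG7 at 2.08 ± 0.15. Interferon response genes fell in 6 of 15 cases, OAS2 by 1.8 ± 0.15 (adjusted p = 0.0856 with an estimated correlation). Immediate early and stress genes fell in 8 of 16 cases, NR4A1 by 1.74 ± 0.12, and rose in 3, FOSB by 1.13 ± 0.13. Platelet surface receptors rose in 3 of 17 cases and fell in 5. Platelet granule and cytoskeletal proteins rose in 3 of 18 and fell in 6 (LTBP1 at 1.64 ± 0.19, MMRN1 at -2.2 ± 0.19). Splicing regulators fell in 9 of 29 cases and rose in 1 (SRSF5 at -1.09 ± 0.14; adjusted p = 0.565 with an estimated correlation). Adjusted over the list alone, 1 more gene rose in the globin, heme, red cell and primary granule lists, 1 more fell in the secondary granule and myeloid transcription factor lists, and the other 14 lists kept their counts.

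In limma 4410 genes (27.6%) changed, 2417 higher and 1993 lower, of which 730 and 510 differed at least 2-fold. With arrays centred on the median gene, which shifted the comparison by -0.1, the split was 2118 higher and 2710 lower, so the larger side depends on the scaling. It also depends on the arrays, with 1850 higher and 1970 lower without Granulopoietic replicate 1, while without Granulopoietic replicate 3 the genes at least 2-fold higher numbered 1107. Groups did not overlap for 39% of genes, where chance gives 10%. Camera called 13 lists at the preset correlation, up to 9 in other splits, and 4 with an estimated one.

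The comparison of Megakaryopoietic with CD34 arrays asked what changed in cells given thrombopoietin with SCF and Flt3-ligand. Genes of the platelet lists were among those that rose most. ITGB3 and ITGA2B, the subunits of the fibrinogen receptor, rose by 7.22 ± 0.11 and 5.26 ± 0.1, LTBP1 by 7.07 ± 0.19, CD226 by 6.59 ± 0.12, LGALSL by 6.58 ± 0.21, PDE3A by 6.35 ± 0.18, PROS1 (protein S) by 6.23 ± 0.18 and PPBP, the precursor of platelet basic protein, by 6.01 ± 0.17. The largest decreases were in 8 genes: S100A8 fell by 6.23 ± 0.53, EVI2B by 5.53 ± 0.2, S100A12 by 5.38 ± 0.17, IFI30 by 5.03 ± 0.25, GLIPR1 by 5 ± 0.26, CD53 by 4.83 ± 0.29, PROM1 by 4.7 ± 0.31 and ANXA1 by 4.61 ± 0.17.

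All 17 measured platelet surface receptors rose, CLEC1B by 5.99 ± 0.12 and SELP (P-selectin) by 5.15 ± 0.18 (adjusted p = 0.00178 with an estimated correlation). Of 18 platelet granule and cytoskeletal proteins 16 rose, VWF by 5.98 ± 0.1 and TUBB1, the tubulin of the platelet marginal band, by 5.53 ± 0.22 (adjusted p = 0.00591 with an estimated correlation). Of 16 erythroid and megakaryocytic transcription factors 6 rose and 4 fell, with GATA1 at 2.45 ± 0.11, TAL1 at 2.44 ± 0.12, MEIS1 at 2.22 ± 0.24 and MYB at -4.2 ± 0.35 (adjusted p = 0.481 with an estimated correlation), and with centred arrays 10 rose and 4 fell. In red cell membrane and skeleton 10 of 19 rose and 6 fell, DMTN by 4.74 ± 0.17, CA2 by 4.12 ± 0.18, SPTB (beta spectrin) by 4.08 ± 0.14 and RHAG by 3.71 ± 0.19 on the rising side (adjusted p = 0.181 with an estimated correlation). With centred arrays 11 rose and 1 fell, so most of the falling calls in this list depend on the scaling. Of 7 globin genes 1 rose, HBD at 2.24 ± 0.13 (adjusted p = 0.374 with an estimated correlation; 3 rose with centred arrays), while HBB differed by 0.35 ± 0.15 (adjusted p = 0.0652). Heme synthesis and iron uptake went both ways, with 3 of 13 up (CPOX at 3.42 ± 0.29, ABCB6 at 3.09 ± 0.18) and 7 down (the transferrin receptor gene TFRC at -2.41 ± 0.32), a direction that turned to 4 up and 3 down with centred arrays. The list's median was -0.38 and its mean 0.06. Cholesterol synthesis rose in 12 of 13 cases, with SQLE at 3.1 ± 0.18 and HMGCS1 at 2.94 ± 0.26 (adjusted p = 0.147 with an estimated correlation).

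All 10 myeloid transcription factors that passed, of 11 measured, fell, including IRF8 at -3.13 ± 0.19, SPI1 at -3.12 ± 0.14 and CEBPB at -2.52 ± 0.18 (adjusted p = 0.0347 with an estimated correlation). Secondary granule proteins and neutrophil maturation fell in 16 of 21 cases, CSF3R by 4.34 ± 0.15 (adjusted p = 0.0546 with an estimated correlation). Primary granule proteins fell in 5 of 11, LYZ by 2.16 ± 0.23 and MPO by 2.1 ± 0.17, with 1 rising, which became 2 rising and 2 falling with centred arrays. Of 9 eosinophil, basophil and mast cell markers 3 fell, CPA3 by 2.49 ± 0.23 and HDC by 2 ± 0.12, and 0 rose. Phagocyte NADPH oxidase genes fell in 3 of 4 cases, CYBB by 3.76 ± 0.3. Monocyte, macrophage and dendritic cell markers fell in 9 of 14, VCAN by 3.57 ± 0.16 and CX3CR1 by 3.33 ± 0.22 (adjusted p = 0.0445 with an estimated correlation). Stem and progenitor cell genes fell in 18 of 24 and rose in 2, with CD34 at -4.59 ± 0.3, HOXA5 at -4.27 ± 0.27, NPR3 at -4.21 ± 0.26 and FLT3 at -4.16 ± 0.21 (adjusted p = 0.24 with an estimated correlation). EPOR rose by 1.15 ± 0.13. KIT differed by -0.51 ± 0.26 (adjusted p = 0.125), and without Megakaryopoietic replicate 3 it passed at -0.8 (adjusted p = 0.0133).

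Cell cycle genes divided, with 12 of 25 up (BUB1 at 2.28 ± 0.31, TOP2A at 2.16 ± 0.29, CCNA2 at 2.1 ± 0.29) and 6 down, MCM5, a component of the replication helicase, at -2.45 ± 0.25 (adjusted p = 0.553 with an estimated correlation). B cell markers fell in 6 of 8 cases, CD79A by 3.15 ± 0.16 (adjusted p = 0.204 with an estimated correlation), and interferon response genes in 11 of 15, OAS2 by 2.84 ± 0.15 (adjusted p = 0.267 with an estimated correlation), which became 6 falling and 1 rising with centred arrays. T and NK cell markers rose in 1 of 14 cases and fell in 2, which became 6 and 1 with centred arrays, and their median (-0.01) ran against the test direction, which was up. Immediate early and stress genes fell in 8 of 16 and rose in 3, with NR4A1 at -1.54 ± 0.12 and FOSB at 1.31 ± 0.13. Splicing regulators fell in 13 of 29 cases and rose in 5, with KHDRBS1 at -1.49 ± 0.17 and RBM38 at 1.74 ± 0.14, and with centred arrays 10 rose and 9 fell. Adjusted over the list alone, 1 more gene rose in the platelet granule, primary granule and cell cycle lists, 1 more fell in the secondary granule, monocyte and splicing lists, T and NK markers had 0 up and 1 down, and the other 13 lists kept their counts.

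In limma 7643 genes (47.8%) changed, 1927 higher and 5716 lower, of which 980 and 2626 differed at least 2-fold. That 74.8% of changed genes were lower depends on the scaling. Centring on the median gene shifted the comparison by 0.32 and gave 5104 higher and 4021 lower (44.1% lower). The median log2 difference was -0.13 as deposited and 0.2 after that centring. At least 2-fold, 1353 were then higher and 1604 lower, so more stayed lower. Quantile normalisation gave 53.8% lower, and centring on genes not used in blood cells, chosen after the data had been seen, gave 77.6% lower. Groups did not overlap for 56.6% of genes, where chance gives 10%. Camera called 13 lists at the preset correlation, up to 11 in other splits, and 4 with an estimated one.

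**Figure D3:**
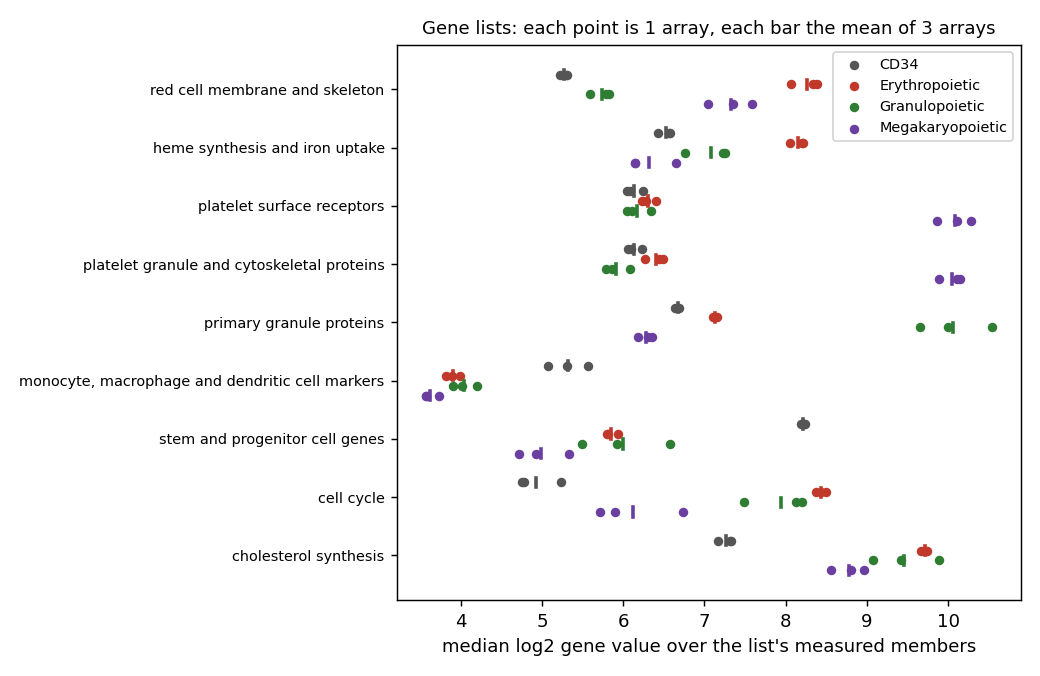
Median log2 gene value over the measured members of 9 gene lists, 1 point per array, 1 colour per group and a bar at the mean of 3 arrays. Red cell genes are highest in Erythropoietic arrays (8.06 to 8.38), platelet receptors in Megakaryopoietic arrays and primary granule genes in Granulopoietic arrays; the heme list, lower in Megakaryopoietic than in CD34 arrays by gene counts of 3 up and 7 down, turns to 4 up and 3 down with centred arrays.

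**Figure D4:**
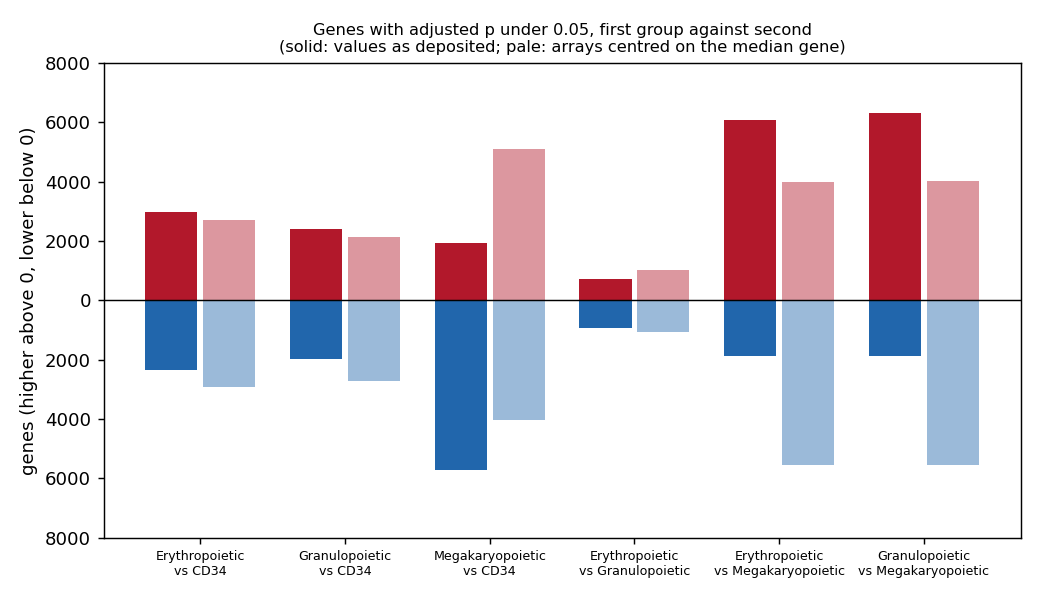
Genes higher (above 0) and lower (below 0) at an adjusted p under 0.05 in the 6 comparisons, solid for values as deposited and pale for arrays centred on the median gene. Megakaryopoietic against CD34 has 1927 higher and 5716 lower genes as deposited and 5104 and 4021 centred. The larger side turns in all comparisons but Erythropoietic against Granulopoietic. Among genes changed at least 2-fold it does not turn in those with Megakaryopoietic.

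Erythropoietic was compared with Granulopoietic to ask which genes parted those 2 lineages, whose media shared interleukin-3. AHSP was higher in Erythropoietic arrays by 4.49 ± 0.18, SLC4A1 by 4.06 ± 0.12, CA1 by 3.06 ± 0.15, ALAS2 by 3.02 ± 0.12 and RHAG by 3.01 ± 0.19. BPI was lower at -6.15 ± 0.16, ELANE at -4.41 ± 0.15, CTSG at -4.35 ± 0.23 and PRTN3 at -4.13 ± 0.12. Red cell membrane and skeleton genes were higher in 15 of 19 cases and lower in 0 (adjusted p = 0.00335 with an estimated correlation), heme synthesis and iron uptake genes in 10 of 13 (adjusted p = 0.033 with an estimated correlation) and globin genes in 4 of 7, HBB by 2.89 ± 0.15. Within the heme list, TFRC was higher by 1.3 ± 0.32 (adjusted p = 0.0174), a call lost without any 1 of Erythropoietic replicates 1, 2 and 3 (adjusted p = 0.057, 0.0555 and 0.0649). Primary granule proteins were lower in 10 of 11 cases and myeloid transcription factors in 9 of 11, with CEBPE at -2.37 ± 0.14 and GFI1 at -2.09 ± 0.12 (adjusted p = 0.000432 for each list with an estimated correlation). Erythroid and megakaryocytic transcription factors were higher in 8 of 16 and lower in 2, with GFI1B at 1.91 ± 0.11 and GATA1 at 1.88 ± 0.11 (adjusted p = 0.0687 with an estimated correlation).

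Platelet surface receptors were higher in Erythropoietic arrays in 8 of 17 cases and lower in 1, with ITGB3 at 1.89 ± 0.11 and ITGA2B at 1.87 ± 0.1 (adjusted p = 0.033 with an estimated correlation), and platelet granule and cytoskeletal proteins in 8 of 18, THBS1 at 2.21 ± 0.12 (adjusted p = 0.0521 with an estimated correlation). Secondary granule proteins and neutrophil maturation were lower in 8 of 21 and higher in 1, with CEACAM6 at -3.83 ± 0.15 and CSF3R at -2.81 ± 0.15 (adjusted p = 0.0444 with an estimated correlation). S100A8, in the same list, was lower at -2.23 ± 0.53, a call lost without Erythropoietic replicate 2 (-1.97, adjusted p = 0.0758). Monocyte markers were lower in 4 of 14 cases (adjusted p = 0.033 with an estimated correlation), and immediate early and stress genes in 7 of 16 with 1 higher, JUN at -1.46 ± 0.25 (adjusted p = 0.0588 with an estimated correlation). In most of the remaining lists few genes passed. Of 9 eosinophil markers 1 was higher and 1 lower, EPX at -1.23 ± 0.24, and of 13 cholesterol synthesis genes 1 was higher and 1 lower. Of 25 cell cycle genes 1 was higher (adjusted p = 0.317 with an estimated correlation), and of 29 splicing regulators 2 were higher, RBM38 by 0.82 ± 0.14 (adjusted p = 0.465 with an estimated correlation). With centred arrays 5 cell cycle genes were higher, and 6 splicing regulators were higher and 1 lower. Of 4 phagocyte NADPH oxidase genes 2 were lower (adjusted p = 0.143 with an estimated correlation). Of 14 T and NK markers 1 was lower, NKG7 at -3.09 ± 0.15, with a median of 0.01 and a mean of -0.24. Of 8 B cell markers 1 was lower, IGLL1 at -1.64 ± 0.15, and of 15 interferon response genes 2 were lower. Stem and progenitor genes were higher in 6 of 24 cases and lower in 3, with ADGRG1 at 1.37 ± 0.16 and KIT at 1.33 ± 0.26, and the list's median (-0.06) and mean (0.09) differed in sign. EPOR was higher by 1.07 ± 0.13. Adjusted over the list alone, 16 red cell, 12 heme and 5 globin genes were higher, as were 9 genes in each platelet list and 1 splicing regulator, and 9 immediate early genes were lower. In the same adjustment 8 stem and progenitor genes were higher and 6 lower, 1 monocyte marker was higher and 6 lower, 8 erythroid and megakaryocytic factors were higher and 3 lower, and 0 cell cycle genes passed. The other 9 lists kept their counts.

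In limma 1629 genes (10.2%) differed, 710 higher and 919 lower in Erythropoietic arrays, of which 208 and 319 differed at least 2-fold. The split was 860 and 846 without Granulopoietic replicate 2, so the larger side turned, and was 639 and 1419 without Granulopoietic replicate 3 and 465 and 689 without Erythropoietic replicate 3. Without Granulopoietic replicate 3 and Megakaryopoietic replicate 1, the arrays with the lowest medians of their groups, the count was 2721, of which 1566 were among the 1629; this alternative was chosen after the data had been seen. Groups did not overlap for 25.8% of genes, where chance gives 10%. Camera called 14 lists at the preset correlation, up to 12 in other splits, and 8 with an estimated one.

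Erythropoietic was compared with Megakaryopoietic to ask which genes parted the lineages that share the factor GATA1. AHSP was higher in Erythropoietic arrays by 5.63 ± 0.18, EPX by 5.56 ± 0.24, CA1 by 4.59 ± 0.15, SLC4A1 by 4.45 ± 0.12, MYB by 4.23 ± 0.35 and TFRC by 4.15 ± 0.32. CD226 was lower at -6.46 ± 0.12, PDE3A at -5.73 ± 0.18, VWF at -5.67 ± 0.1 and CLEC1B at -5.59 ± 0.12. All 17 platelet surface receptors and all 18 platelet granule and cytoskeletal proteins were lower, GP1BA at -4.4 ± 0.13, CD9 at -4.15 ± 0.13 and TUBB1 at -5.18 ± 0.22 (adjusted p = 0.00142 and 0.00417 with an estimated correlation). All 25 cell cycle genes were higher, with MCM5 at 3.47 ± 0.25 and CDC6 at 3.38 ± 0.3 (adjusted p = 0.445 with an estimated correlation). Heme genes were higher in 9 of 13 cases and lower in 2, FECH at 3.33 ± 0.18 (adjusted p = 0.597 with an estimated correlation), globin genes in 5 of 7 with 1 lower, and red cell membrane genes in 13 of 19 with 3 lower. The transcription factors of the erythroid and megakaryocytic list were higher in 6 cases and lower in 6, MEIS1 at -3.62 ± 0.24, and with centred arrays 5 were higher and 9 lower.

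Primary granule proteins were higher than in Megakaryopoietic arrays in 9 of 11 cases, MPO by 3.43 ± 0.17 (adjusted p = 0.348 with an estimated correlation). The same held for myeloid transcription factors in 8 of 11, SPI1 by 2.11 ± 0.14 (adjusted p = 0.283 with an estimated correlation), and eosinophil, basophil and mast cell markers in 7 of 9, CPA3 by 3.79 ± 0.23 and HDC by 3.43 ± 0.12 (adjusted p = 0.283 with an estimated correlation). Stem and progenitor genes were higher in 13 of 24 and lower in 2, with KIT at 1.47 ± 0.26. With centred arrays 5 primary granule genes, 6 myeloid factors and 5 eosinophil, basophil and mast cell markers were higher, and 8 stem and progenitor genes were higher and 3 lower. Several weaker list directions turned with the scaling: secondary granule genes had 5 higher and 0 lower but 2 and 5 with centred arrays, monocyte markers 1 and 0 but 0 and 8, T and NK markers 1 and 0 but 0 and 6, and of 15 interferon response genes 7 were higher, which became 0. For the secondary granule, monocyte and T and NK lists the medians (0.15, 0.07 and 0.09) were positive and the test direction was down. Of 4 phagocyte NADPH oxidase genes 2 were higher and of 8 B cell markers 3, while with centred arrays each of these lists had 1 higher and 1 lower. Of 13 cholesterol synthesis genes 7 were higher and 3 lower. Of 16 immediate early genes 5 were higher and 7 lower, with ZFP36 at -2.61 ± 0.12 (adjusted p = 0.348 with an estimated correlation), which became 2 and 9 with centred arrays. Of 29 splicing regulators 13 were higher and 4 lower, with SRSF7 at 2.19 ± 0.22 and RBM38 at -1.62 ± 0.14, which became 12 and 10 with centred arrays. EPOR was higher by 0.43 ± 0.13 (adjusted p = 0.0141), a call lost with centred arrays at 0.02. Adjusted over the list alone, 9 myeloid transcription factors, 14 stem and progenitor genes, 8 interferon genes and 8 cholesterol genes were higher, and 8 immediate early genes, 4 cholesterol genes and 5 splicing regulators were lower. The other 14 lists kept their counts.

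In limma 7984 genes (49.9%) differed, 6091 higher and 1893 lower in Erythropoietic arrays, of which 3072 and 934 differed at least 2-fold. The share of lower genes, 23.7%, was 58.1% with centred arrays (shift -0.4), 47.8% with quantile normalisation and 22.2% with centring on genes not used in blood cells. Groups did not overlap for 60.5% of genes, where chance gives 10%. Camera called 8 lists at the preset correlation, up to 6 in other splits, and 2 with an estimated one; without Granulopoietic replicate 3, Megakaryopoietic replicate 1 or Megakaryopoietic replicate 3 the preset count was 5.

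Granulopoietic was compared with Megakaryopoietic for the same question in the remaining pair. EPX was higher in Granulopoietic arrays by 6.79 ± 0.24, BPI by 6.23 ± 0.16, MPO by 5.92 ± 0.17, SERPINB10 by 5.62 ± 0.16 and ELANE by 5.52 ± 0.15. CD226 was lower at -6.79 ± 0.12, PDE3A at -6.48 ± 0.18, VWF at -6.44 ± 0.1, SELP at -6.2 ± 0.18 and ITGB3 at -5.72 ± 0.11. All 17 platelet surface receptors and all 18 platelet granule and cytoskeletal proteins were lower (adjusted p = 0.00107 and 0.00323 with an estimated correlation). All 11 primary granule proteins and 9 of 11 myeloid transcription factors were higher, SPI1 by 3.38 ± 0.14, GFI1 by 3.13 ± 0.12, CEBPA by 2.87 ± 0.13 and CEBPE by 2.73 ± 0.14 (adjusted p = 0.0113 for each list with an estimated correlation). Eosinophil, basophil and mast cell markers were higher in 7 of 9 cases, CLC by 5.14 ± 0.29 (adjusted p = 0.191 with an estimated correlation). Cell cycle genes were higher in 23 of 25, MCM5 by 3.29 ± 0.25 (adjusted p = 0.548 with an estimated correlation), and secondary granule genes in 11 of 21 with 1 lower, CEACAM6 by 4.34 ± 0.15 and CSF3R by 4.12 ± 0.15. Erythroid and megakaryocytic transcription factors were lower in 10 of 16 and higher in 5, MEIS1 at -4.85 ± 0.24 and MYB at 4.52 ± 0.35 (adjusted p = 0.259 with an estimated correlation), and red cell membrane genes were lower in 9 of 19 and higher in 5, DMTN at -3.55 ± 0.17 (adjusted p = 0.312 with an estimated correlation), which became 11 lower and 2 higher with centred arrays.

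Heme genes were higher in Granulopoietic arrays in 9 of 13 cases and lower in 3, ABCB6 at -3.04 ± 0.18, which became 5 and 4 with centred arrays. The globin list had 3 higher and 1 lower, HBD at -1.17 ± 0.13, which became 1 and 2 with centred arrays, and the splicing regulators had 12 higher and 6 lower, RBM38 at -2.44 ± 0.14, which became 7 and 13. T and NK markers had 2 higher, NKG7 at 3.85 ± 0.15 among them, and became 1 higher and 6 lower with centred arrays. In these 3 lists the medians (0.35, 0.19 and 0.03) were positive and the test direction was down. Of 4 phagocyte NADPH oxidase genes 3 were higher, of 14 monocyte markers 7, of 8 B cell markers 3 and of 15 interferon response genes 5, with 0 lower in each. With centred arrays the monocyte markers had 3 higher and 2 lower and the interferon genes 4 and 3. Stem and progenitor genes were higher in 14 of 24 cases and lower in 4, with CD34 at 1.67 ± 0.3, and cholesterol synthesis genes were higher in 8 of 13 and lower in 3, which became 5 and 5 with centred arrays. Of 16 immediate early genes 4 were higher and 4 lower, against 2 and 8 with centred arrays, and their median (0.13) was positive while the test direction was down. KIT differed by 0.14 ± 0.26, which did not pass (adjusted p = 0.698). EPOR was lower at -0.64 ± 0.13. Adjusted over the list alone, all 11 myeloid transcription factors, 8 of the eosinophil, basophil and mast cell markers and 1 of the T and NK markers were higher, and 2 globin genes were lower. The other 16 lists kept their counts.

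In limma 8198 genes (51.2%) differed, 6324 higher and 1874 lower, of which 3116 and 991 differed at least 2-fold. The share of lower genes, 22.9%, was 58% with centred arrays (shift -0.42), 46.4% with quantile normalisation and 24% with centring on genes not used in blood cells. Groups did not overlap for 53.1% of genes, where chance gives 10%. Camera called 8 lists at the preset correlation and 4 with an estimated one, while other splits gave up to 10, so the preset calls do not separate this comparison from other splits.

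The 3 comparisons with CD34 were set side by side to ask how much change the lineages shared. Genes such as S100A8, S100A12, DNTT, HOXA5 and VCAN fell in all 3, and HMGCS1, SQLE, TOP2A and RHAG rose in all 3. Erythropoietic and Granulopoietic shared 1689 higher and 1568 lower genes, with 96 in opposite directions, where independent lists would share 452, 291 and 725. Erythropoietic and Megakaryopoietic shared 657 higher and 1756 lower genes, with 1326 opposite, against 360, 834 and 1350 for independent lists. Granulopoietic and Megakaryopoietic shared 470 higher and 1417 lower genes, with 1161 opposite, against 291, 712 and 1103. In all 3 lineages 365 genes rose and 1199 fell, where independent lists would give 54 and 104. Among genes changed at least 2-fold the shared counts were 868, 729 and 469 for the pairs and 396 for all 3. Unchanged groups simulated around the CD34 means shared 0 calls on average, but had hardly any calls to share, so this decides nothing. The correlation across genes of the log2 differences was 0.797, 0.349 and 0.239 for the pairs in the same order. Simulated unchanged groups gave 0.499 to 0.501 from the shared CD34 arrays alone, which is no reference for changed genes. The covariances were 0.319, 0.227 and 0.136, against 0.0137 simulated for each. The 3 CD34 arrays cannot be divided into sets of at least 2, so part of the sharing may come from the shared controls.

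Exon use was compared to ask where probe sets of a gene changed unequally. In Megakaryopoietic against CD34, VWF rose by 5.98 while its probe set 3441809 stayed at 6.43 ± 0.34 against 6.25 ± 0.27 (SD, n = 3), a difference of 0.18. ITGA2B rose by 5.26 and its probe set 3759180 by 1.58, from 10.48 ± 0.053 to 12.05 ± 0.088, a probe set already bright in CD34 arrays. PTPRJ, which encodes a receptor tyrosine phosphatase, rose by 4.6 while its probe set 3329986 differed by 0.15. ABCC4 rose by 4.56 while its probe set 3521306 differed by 0.27, and the homeobox gene HLX fell by 1.26 while its probe set 2381388 fell by 6. Both tests called 2893 of 6367 tested genes, from 3346 by diffSplice and 3421 with a variance for each probe set. The most deviating probe set deviated against the gene's own change in 74% of called genes changed at least 2-fold and in 50.3% of the others. In 25 genes a probe set and its gene moved at least 2-fold in opposite directions.

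**Figure D5:**
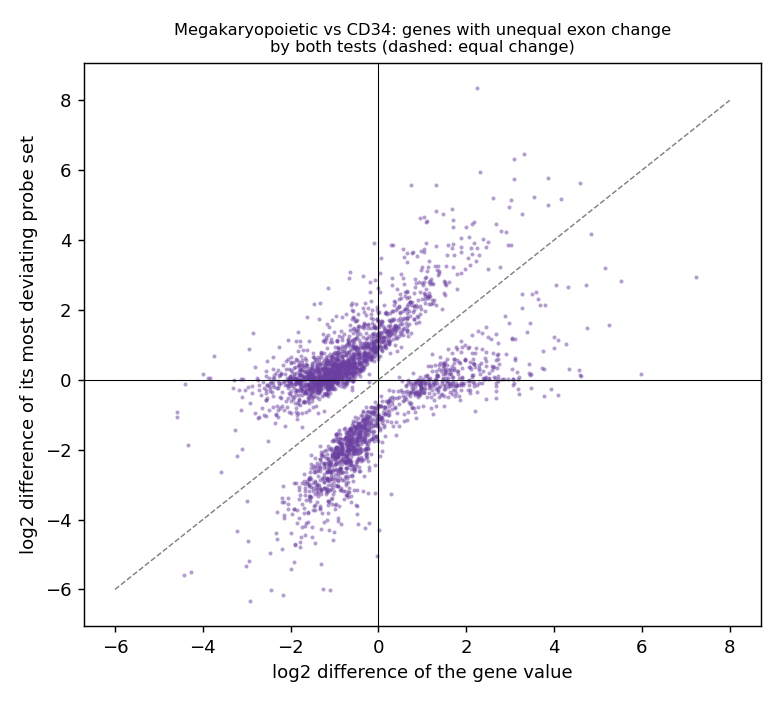
Log2 difference of the gene value (horizontal) and of its most deviating probe set (vertical) for the 2893 genes called by both exon tests in Megakaryopoietic against CD34, with 1 point per gene and a dashed line of equal change. Among genes changed at least 2-fold, 74% have a probe set that deviates against the gene.

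In Erythropoietic against CD34 both tests called 1508 of 7301 genes, from 2314 by diffSplice. FADS2, a fatty acid desaturase gene, rose by 2.49 while its probe set 3333249 differed by -0.32. The splicing factor gene SF1 differed by -0.68 while its probe set 3377081 differed by -3.98, and the calcium pump gene ATP2A3 differed by -0.21 while its probe set 3741808 differed by -1.98. NOTCH1 fell by 2.27 with its probe set 3230220 at 0.41, and FCN2 differed by -0.09 with its probe set 3193646 at -5.06. In Granulopoietic against CD34 both tests called 857 of 7406 genes, from 1429 by diffSplice. The same ATP2A3 probe set differed by -2.27 and its gene by -0.31, NT5C2 differed by 0 with its probe set 3304629 at 2.98, PRTN3 rose by 5.02 with its probe set 3815230 at 7.55, and ELANE rose by 5.44 with its probe set 3815239 at 1.91. Without Granulopoietic replicate 3 and Megakaryopoietic replicate 1 the diffSplice count was 2260. Deviations ran against the gene in 72.9% and 75% of called genes changed at least 2-fold in these comparisons and in 52.5% and 54% of the others.

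Between Erythropoietic and Granulopoietic both tests called 175 of 7698 genes, from 372 by diffSplice and 207 with a variance for each probe set, and diffSplice counts were 226 and 230 without Erythropoietic replicate 2 or 3. ANK1 (ankyrin) was higher by 2.49 with its probe set 3133049 at -0.15, KBTBD11 was at -0.9 with its probe set 3082980 at -3.65. LOXL1 was at -1.16 with its probe set 3601372 at -3.75, and RHOU was at -1.16 with its probe set 2384414 at -3.23. Between Erythropoietic and Megakaryopoietic both tests called 2835 of 6426 genes, from 3253 by diffSplice. SEPTIN5 was at -3.54 with its probe set 3936958 at 0.98, DGKD at -3.86 with its probe set 2532895 at 0.27, and COL18A1 at 0.54 with its probe set 3924227 at 3.91. Between Granulopoietic and Megakaryopoietic both tests called 2830 of 6411 genes, from 3231 by diffSplice. SEPTIN5 was at -4.85 with the same probe set at 1.03, and LOXL1 at 1.54 with its probe set 3601377 at 6.91. ADCY6 was at -4.93 with its probe set 3453290 at -0.93, LTBP1 was at -5.43 with its probe set 2476517 at 0.62 and PTGS1 (cyclooxygenase-1) at -3.94 with its probe set 3188113 at 0.09. Without the requirement that the gene be above the median in both groups, diffSplice called 5562 genes in Megakaryopoietic against CD34, 5438 in Erythropoietic against Megakaryopoietic and 5395 in Granulopoietic against Megakaryopoietic.

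Of the 28 genes known to be spliced by cell type, both tests called 8 of 24 tested in Erythropoietic against CD34, 5 of 24 in Granulopoietic against CD34 and 15 of 23 in Megakaryopoietic against CD34. DiffSplice alone called 12, 9 and 16, and adjusted over the list alone 12, 10 and 17. Among them, probe set 3597348 of TPM1, a tropomyosin gene, differed by -0.54 in Megakaryopoietic against CD34 while TPM1 rose by 2.46, and probe set 3326668 of the adhesion receptor gene CD44 fell by 1.43 while CD44 fell by 3.27. Probe set 3976833 of GATA1 differed by 0.82 in Erythropoietic and 0.79 in Megakaryopoietic against CD34 while GATA1 rose by 2.55 and 2.45. Between lineages both tests called 3 of 25 in Erythropoietic against Granulopoietic, 13 of 24 in Erythropoietic against Megakaryopoietic and 16 of 24 in Granulopoietic against Megakaryopoietic, and adjusted over the list alone diffSplice called 7, 15 and 19. No exon position came with the values, so none of these probe sets could be placed in a transcript, and a bright probe set that does not follow its gene is counted here as unequal change.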

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

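In this part, the tests of a scaling shift, of lost expression, of exon deviation by size of the gene's change, of probe sets that stay still and of the eosinophil granule genes were chosen after the result was seen, whereas the test of signal loss, the own test of probe sets moving against their gene and the other splits were set before it.

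Some genes changed against CD34 in opposite directions in 2 lineages. Each also differed between the lineages in limma, almost by construction. There were 96 between Erythropoietic and Granulopoietic arrays, 38 of them higher and 58 lower in Erythropoietic arrays. There were 1326 between Erythropoietic and Megakaryopoietic arrays, 1106 of them higher and 220 lower in Erythropoietic arrays, and 1161 between Granulopoietic and Megakaryopoietic arrays, 902 higher and 259 lower in Granulopoietic arrays. Those with both changes at least 2-fold numbered 8, 144 and 132. Probe sets without a gene symbol of their own, which entered no comparison, also held signal: 2461 of 25734 (9.6%) stood at least 2-fold above CD34 in a lineage, 1159 in Erythropoietic, 807 in Granulopoietic and 1392 in Megakaryopoietic arrays.

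More genes were lower than higher in Megakaryopoietic against CD34 arrays. A scaling shift of whole arrays cannot be told apart from a loss of expression in the megakaryopoietic cells. The medians of bright genes (-0.48 over 4001 genes) and of genes not used in blood cells (0.08 over 249) lay 0.55 apart, and 77.6% of changed genes were lower with arrays centred on the latter, but those genes lie near background (median 3.01, against 5.61 for all genes), where neither test decides. Centring on the median gene gave 44.1% lower. The signal loss that sets Granulopoietic replicate 3 apart stays open. Its deviation correlated across genes at 0.12 with the Megakaryopoietic difference (0.25, 0.11 and -0.01 for single arrays), where lineage change can mask a loss. Within groups it correlated at 0.63 with that of Megakaryopoietic replicate 1.

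Many genes showed unequal exon change in Megakaryopoietic against CD34 arrays, and the explanation weighed was probe sets that do not follow their gene. For called genes changed at least 2-fold it stays open, as the most deviating probe set deviated against the gene in 74%, and many of these calls may come from probe sets that respond little. For called genes changed under 2-fold the share of deviations against the gene, 50.3%, decided nothing. In 1127 of these 1506 genes (74.8%) the probe set lay more than 2 SE outside the same range. A still probe set in such a gene deviates too little to be called, so calling by itself selects probe sets outside the range. The share therefore does not decide the question, and shows only that these 1127 probe sets moved beyond that range. For the 25 genes in which probe set and gene moved at least 2-fold in opposite directions, 23 had a probe set that passed its own test, which decides nothing, as the genes were selected for that movement. Probe sets that respond to another gene were not tested, and no exon positions were at hand, so a change of exon use stays open in all 3 sets.

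Eosinophil granule genes were higher in Erythropoietic cultures than in CD34 arrays. Cells of the Granulopoietic type as a whole were argued against, because on the linear scale the other granule genes reached a median of 3.23% of their Granulopoietic rise (highest CTSC at 24.6% and MPO at 11.5%, lowest LYZ at -48.1%), while EPX reached 42% and CLC 67.6%. Eosinophil, basophil or mast cell precursors remain open, with 6 of 9 measured markers up. Interleukin-3, present in the Erythropoietic and Granulopoietic media, cannot be told apart from the other factors that differ between the media, although 0 of the 9 markers rose in Megakaryopoietic arrays, whose medium lacked it, by limma's p adjusted over all genes or over the list alone (1 with centred arrays). Neither hypothesis was tested on other samples.

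For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave the highest count of changed genes, 1 of 10 splits, in each comparison: 5327, 4410, 7643, 1629, 7984 and 8198 genes for Erythropoietic, Granulopoietic and Megakaryopoietic against CD34, Erythropoietic against Granulopoietic and Megakaryopoietic, and Granulopoietic against Megakaryopoietic, where the highest other splits gave 1, 0, 0, 0, 0 and 0. For genes with unequal exon change by diffSplice the real counts, again 1 of 10, were 2314, 1429, 3346, 372, 3253 and 3231 and the highest others 66, 861, 93, 56, 10 and 455. For gene list calls the real counts were 14, 13, 13, 14, 8 and 8 and the highest others 12, 9, 11, 12, 6 and 10, so in the last comparison 4 of 10 splits gave as many.

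Among 100 regroupings of the 12 arrays, 1, the real one, gave as many as 9585 genes in the F test, and the highest other gave 5676. For the genes specific to Granulopoietic (120) and Megakaryopoietic (659) as many came in 1 of 100 each, with highest others of 45 and 0. These shares argued against chance. For CD34 (296) and Erythropoietic (71) as many came in 2 of 100 each. There the highest others, 735 and 715, were above the real counts, so chance was not excluded for these 2 sets. The regroupings with 5676, 735 and 715 kept the 3 Megakaryopoietic arrays together under another group's name, which points to that lineage as the main structure of the samples. Besides the real grouping, 2 of the 100 kept them together. The shares for CD34, Erythropoietic and Megakaryopoietic therefore rest largely on how rarely that happened. With those arrays apart the highest counts were 267 for CD34, 0 for Erythropoietic and 0 for Megakaryopoietic.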

How the results depend on the processing

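Alternatives with an estimated list correlation, arrays centred on the median gene, quantile normalisation, bright probe sets, the block and left-out replicates were planned, whereas a variance per probe set, centring on genes not used in blood cells, keeping symbols of several loci and leaving out Granulopoietic replicate 3 with Megakaryopoietic replicate 1 were chosen after the data had been seen.

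With an estimated correlation the gene lists called fell to 3 for Erythropoietic, 4 for Granulopoietic and 4 for Megakaryopoietic against CD34, 8 for Erythropoietic against Granulopoietic, 2 for Erythropoietic against Megakaryopoietic and 4 for Granulopoietic against Megakaryopoietic. Asking for a 2-fold change, a stricter rule by construction, left 868, 729 and 469 shared genes for the pairs in the order above and 396 for all 3. With probe sets above the median only, 5 lists were called in Erythropoietic against Megakaryopoietic and 74 genes were specific to Granulopoietic. With arrays centred on the median gene PRF1 in Granulopoietic against Megakaryopoietic went from 0.42 to 0 (adjusted p = 0.992), as that scaling shifts the comparison by -0.42. Leaving out Granulopoietic replicate 3 and Megakaryopoietic replicate 1 gave 2721 genes in Erythropoietic against Granulopoietic (1566 shared). DiffSplice then called 2260 genes with unequal exon change in Granulopoietic against CD34 (1184 shared). A variance per probe set gave 207 genes with unequal exon change in Erythropoietic against Granulopoietic (175 shared). With no expression requirement, which tests more genes, diffSplice called 5562 in Megakaryopoietic against CD34, 5438 in Erythropoietic against Megakaryopoietic and 5395 in Granulopoietic against Megakaryopoietic. Apart from the widened gene set and the 2-fold rule, the cause was not tested.

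Leaving out 1 array at a time gave 8920 to 10224 genes in the F test. Changed genes ranged over 4257 to 6376, 3416 to 5470 and 6935 to 8362 for Erythropoietic, Granulopoietic and Megakaryopoietic against CD34, 1132 to 2058 for Erythropoietic against Granulopoietic, 7225 to 8614 for Erythropoietic against Megakaryopoietic and 7510 to 8541 for Granulopoietic against Megakaryopoietic. In the same order list calls ranged over 14 to 14, 12 to 16, 11 to 13, 13 to 15, 5 to 9 and 8 to 9. Genes with unequal exon change by diffSplice alone ranged over 1602 to 3003, 968 to 1860, 2808 to 3897, 226 to 430, 2623 to 3721 and 2622 to 3616. The genes called by both exon tests were not recounted with arrays left out. Specific genes ranged over 272 to 328 for CD34, 61 to 114 for Erythropoietic, 97 to 172 for Granulopoietic and 607 to 745 for Megakaryopoietic. Shared genes ranged over 2543 to 4098, 2031 to 2838 and 1492 to 2069 for the pairs and 1269 to 1774 for all 3. The changes of over 1.5 times were 114 Erythropoietic-specific genes without Granulopoietic replicate 2, 5 lists in Erythropoietic against Megakaryopoietic without Granulopoietic replicate 3 or Megakaryopoietic replicate 1 or 3, and 226 and 230 diffSplice calls in Erythropoietic against Granulopoietic without Erythropoietic replicate 2 or 3. By direction they were also 1107 genes at least 2-fold higher in Granulopoietic against CD34 and 1419 lower in Erythropoietic against Granulopoietic, each without Granulopoietic replicate 3, and 465 higher in the latter without Erythropoietic replicate 3.

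Arrays share replicate numbers, but same-numbered arrays did not deviate together: their mean correlation was -0.07 over 18 pairs (-0.62 to 0.21), against 0.04 over 36 other pairs (-0.48 to 0.63), and 0 of 12 arrays correlated best with their own number. With the replicate block the F test called 9147 genes, the 6 comparisons 4832, 3850, 7308, 1343, 7628 and 7837, the list tests 14, 14, 13, 14, 8 and 8 and diffSplice 2061, 1233, 3146, 323, 3030 and 2992, and no count moved by over 1.5 times. Of 1800 single list values 1710 stayed on their side of the threshold, 75 became weaker and 15 stronger. These cover the estimated correlation, bright probe sets, the block and left-out arrays, but no centring or quantile normalisation. Of 12614 named gene values over the other settings 12379 stayed, 144 became weaker and 90 stronger, and 1, PRF1, reached 0 and lost its call. All 632 named exon values stayed, which decides little, as these genes were chosen for the lowest Simes p. Exon values were counted only where gene and probe set were still tested, 19 of 30 with probe sets above the upper quartile. The log2 pseudocount alternative was not run, as the values are already on a log scale. The deposited values give no signal over background for single probe sets, so how far dim genes are limited by it is unknown.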

Other observations

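The 5 lists in this part, like the tests on them, were chosen after the data had been seen, and their counts describe these arrays alone. HOXA and HOXB homeobox genes, which are active in stem and progenitor cells, fell in 8 of 19 cases and rose in 1 in Erythropoietic against CD34 arrays, in the same numbers in Granulopoietic arrays, and in 12 of 19 with 0 rising in Megakaryopoietic arrays (adjusted p = 0.0351, 0.0243 and 0.0492 with an estimated correlation). HOXA9 fell by 1.54 ± 0.22 (SE, n = 3 against 3) in Erythropoietic and by 3.43 ± 0.22 in Megakaryopoietic arrays, and HOXA6 fell by 2.24 ± 0.15 and 2.91 ± 0.15. Genes of lysosomal and antigen processing proteins fell in 9 of 15 cases and rose in 2 in Erythropoietic arrays, fell in 6 and rose in 6 in Granulopoietic arrays, and fell in 10 and rose in 4 in Megakaryopoietic arrays (adjusted p = 0.164, 0.673 and 0.546 with an estimated correlation). In Megakaryopoietic arrays the cathepsin gene CTSS fell by 4.14 ± 0.28, and CIITA, the activator of MHC class II genes, and the invariant chain gene CD74 fell by 3.11 ± 0.12 and 3.11 ± 0.19, while the protease gene LGMN rose by 3.98 ± 0.18.

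Serine and one-carbon synthesis genes rose in 13 of 15 cases in both Erythropoietic and Granulopoietic against CD34 arrays, and in Megakaryopoietic arrays 6 rose and 4 fell (adjusted p = 0.141, 0.0821 and 0.546 with an estimated correlation), with a median of -0.02 and an upward test direction there. PSAT1 rose by 3.72 ± 0.17, 4.22 ± 0.17 and 1.17 ± 0.17 in the 3 lineages, whereas PHGDH, which starts serine synthesis, rose by 1.03 ± 0.16 and 2.04 ± 0.16 in Erythropoietic and Granulopoietic arrays and fell by 1.22 ± 0.16 in Megakaryopoietic arrays. Cytosolic aminoacyl-tRNA synthetases rose in 12 and 8 of 15 cases in Erythropoietic and Granulopoietic arrays, and in Megakaryopoietic arrays 1 rose and 10 fell (adjusted p = 0.281, 0.33 and 0.546 with an estimated correlation). AARS1 rose by 1.72 ± 0.17 and 1.06 ± 0.17 in Erythropoietic and Megakaryopoietic arrays, and KARS1 fell by 1.93 ± 0.16 in Megakaryopoietic arrays. Glycolysis genes rose in 11 and 9 of 16 cases in Erythropoietic and Granulopoietic arrays, and in Megakaryopoietic arrays 7 rose and 3 fell (adjusted p = 0.283, 0.33 and 0.546 with an estimated correlation). The aldolase gene ALDOC rose by 2.17 ± 0.18 in Erythropoietic and 3.22 ± 0.18 in Megakaryopoietic arrays, and the glucose transporter gene SLC2A3 rose by 2.59 ± 0.15 in Megakaryopoietic arrays.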
